A study of Oryza sativa with 6 samples.

How the data were processed

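Root RNA was sequenced from 6 samples of rice (Oryza sativa, cultivar Kitaake), 3 from plants grown alone and 3 from plants grown with the floating fern Azolla filiculoides. Per the labels' protocols, seedlings 13 days old were moved into hydroponic boxes of 4 plants and about 5 L of Yoshida nutrient solution, under 14 h of light at 220 µmol m−2 s−1 and 25/19 °C for day and night. RNA came from the distal parts of the roots, up to 1 cm from the tip, at 15 DAT, and poly-A RNA was made into strand-specific libraries with the dUTP method. The labels call the 3 samples of a group biological replicates, with boxes as the replicate unit.

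The deposited table held 1 column of estimated counts per library for 37863 gene loci with RAP-DB identifiers, in which the digits after "Os" give the chromosome. Most of these values were whole, and between 1343 and 1409 loci per library held a value more than 1e-06 away from a whole number, as tools that divide reads between similar loci give. The values were not scaled between libraries, since the column totals differed. Per the submitters' processing notes, the authors used the IRGSP-1.0 build and DESeq2 1.28.1. The aligner, the counting tool, its strand setting and any filter are not given in the sources used here. Whole counts had been assumed when the tests were chosen, so the estimated counts as deposited by the authors were rounded to whole numbers before every count-based test, and the count model was kept. Each column was tied to its sample by the label that carries the column's name, and 0 columns were left over.

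The totals ran from 21551508 to 25120456 estimated counts per library. Of the 37863 loci, 5410 were at 0 in all 6 libraries, and 24615 passed edgeR's filterByExpr and were tested. Values per library were scaled to CPM with TMM factors, and means are given with the standard deviation over 3 libraries. Where a group held at most 3 counts of a locus, the ratio of the groups is given with an exact 95% interval, or as a lower bound against a floor of 3 counts over the group; such intervals and bounds cover counting error alone.

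The comparison of co-cultivated with control libraries was fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F test, group as the single term, two-sided). A locus counts as called, higher or lower, when its Benjamini-Hochberg adjusted p over all 24615 loci was under 0.05. All 6 libraries entered the fit, with 4 residual degrees of freedom. Gene lists were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 21 lists with at least 5 tested members, and again with the correlation estimated per list and with fry. Calls adjusted over the list alone are given beside those over all loci.

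The 25 lists, with 265 pairs of symbol and locus, the rule for named genes, the main design and most alternatives were fixed before the data were examined. The table does not pair its identifiers with names, and no annotation of IRGSP-1.0 was used here. A gene table of the assembly ASM3414082v1 shared 1 identifier with the count table, so each pair was checked by position: the symbol had to lie on the chromosome that the locus names and in the same order as the other members. Of the 265 pairs, 170 passed, 6 symbols had several entries, 2 were out of order and 83 were not in the gene table. The 4 whose symbol lay on another chromosome (TOM1, IRO2, CRL4 and CYP76M7) were left out before any test, which left 261. Genes that passed are named plainly; the others are given with their locus as "listed as", since their names rest on the fixed list alone. Another 16 lists defined by gene descriptions could not be built and were dropped. Coordinates are not printed, because the builds differ.

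Genes were named by a rule: up to 10 in each direction with the largest fold change among called genes with a mean log2 CPM of at least 1, no overlap between the groups and a checked symbol, which gave 8 higher and 8 lower, and in each list the up to 3 members with the smallest p. Both parts together gave 80 genes. Unnamed loci are limited to the extreme 2 in each direction under the same criteria. Other members are named where a count needed it, after their values were seen.

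Replicates were compared before averaging: the chi-square per locus between 2 libraries of a group, which is near 1 for sampling noise, ran from 23.1 to 119, so no pair was counted as 1 library. The test was tried on data simulated for this comparison over 24615 loci, in which known loci were changed. It recovered 0 of 50 loci changed 1.5-fold, 8 of 50 changed 2-fold, 32 of 50 changed 4-fold and 45 of 50 changed 8-fold, all in the right direction, and 5 of its 90 calls (5.56%) were false. Changes of 2-fold and less are therefore mostly below what 3 libraries per group could call.

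The alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other count filters, a robust fit, the 20 most abundant loci left out, a replicate block, 2 other thresholds and each library left out in turn. A cell-division score as a covariate, lists of checked symbols alone and the ratios and bounds of low-count loci without 1 library were added after seeing the data.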

Results

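The transcriptome of rice root tips was measured in plants grown alone (control) and in plants grown with Azolla filiculoides (co-cultivated), a floating fern that carries nitrogen-fixing cyanobacteria and is used as a green manure in paddies. The comparison asks how the fern's presence on the nutrient solution changes gene expression in the roots below it. Each group held 3 libraries, with totals of 21551508 to 23703813 estimated counts in the control group and 23477086 to 25120456 in the co-cultivated group. The surface of the control boxes was covered against algae, so the groups differ in that cover as well as in the fern.

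Co-cultivated root tips had far lower levels of several transcripts with which rice takes up iron. IRT1, the main ferrous iron transporter of rice roots, fell from 172 ± 54.6 CPM (SD, n = 3) in the control group to 0.906 ± 0.461 CPM (n = 3) in the co-cultivated group, a log2 fold change of −7.55 ± 0.46 (SE, edgeR adjusted p = 0.00114). VIT2, a transporter that moves iron into the vacuole, rose from 3.98 ± 1.84 to 270 ± 37.7 CPM, a log2 fold change of 6.08 ± 0.42 (edgeR adjusted p = 0.00149). SPX2 and PT6, genes of the phosphate starvation response, were called higher, as was a locus listed as the nitrate reductase NIA2, and HB2, a non-symbiotic haemoglobin, was called lower. In all, 360 loci were called higher and 288 lower of the 24615 tested. The counts depended on which library was left out: they were 65 higher and 83 lower without control replicate 1, 361 and 493 without control replicate 2, 204 and 195 without control replicate 3, 56 and 86 without co-cultivated replicate 1, 226 and 126 without co-cultivated replicate 2, and 170 and 118 without co-cultivated replicate 3. DESeq2 called 1486 higher and 938 lower.

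**Figure D1:**
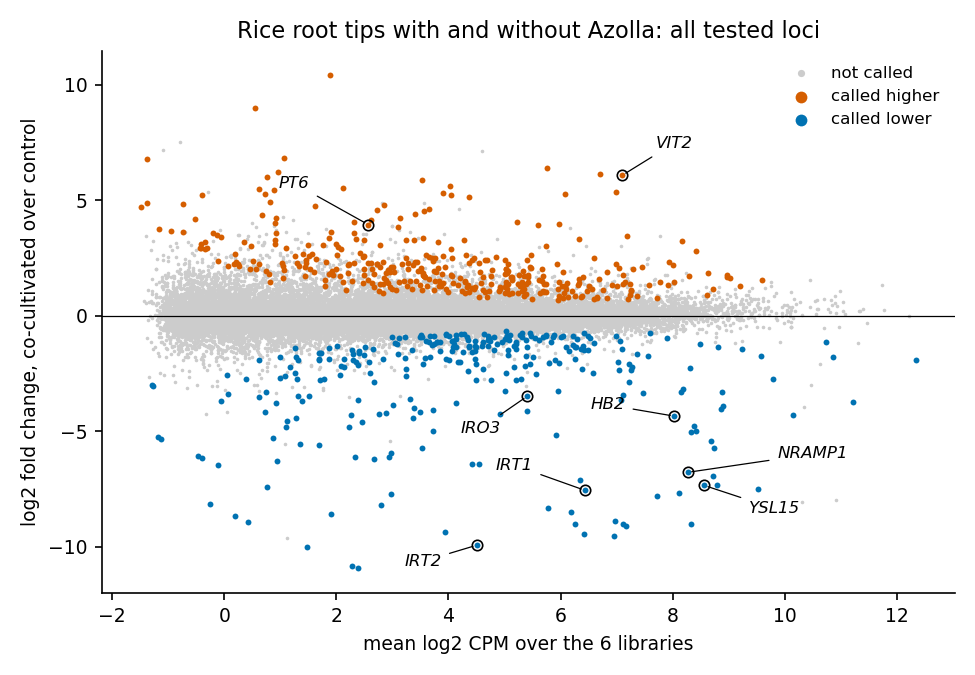
Log2 fold change (co-cultivated over control) against the mean log2 CPM over the 6 libraries for the 24615 tested loci, with the 360 called higher in orange, the 288 called lower in blue and 8 named genes circled. The iron transporter genes IRT1, NRAMP1 and YSL15 lie between −6.77 and −7.55; fitted values of loci at 0 counts in a whole group depend on the prior count and are no bounds.

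The iron deficiency list, genes induced when rice roots lack iron, was lower by camera (adjusted p = 9.79e-22) and by fry (adjusted p = 0.00679), but did not pass camera with an estimated correlation (adjusted p = 0.417). Of its 15 tested members, 12 were called lower and 0 higher, 14 were lower adjusted over the list alone, and all 15 had a negative fold change, with a median of −7.34. These loci held 1.105% ± 0.359 of all counts in the control libraries (SD, n = 3) and 0.0170% ± 0.00580 in the co-cultivated libraries (n = 3). NRAMP1, a metal transporter, fell from 611 ± 201 to 5.60 ± 3.52 CPM (log2 fold change −6.77 ± 0.57, edgeR adjusted p = 0.00330). IRO3, a transcription factor gene of the iron response, fell from 77.8 ± 25.1 to 7.003 ± 1.39 CPM (log2 fold change −3.47 ± 0.28, edgeR adjusted p = 0.00298). IRT2, a further ferrous iron transporter gene, held 3144 counts over the control libraries and 3 over the co-cultivated ones, a ratio of 1115 with a 95% counting interval of 381 to 5409.7 (edgeR adjusted p = 0.00330). Without co-cultivated replicate 3 this ratio was 727, and without co-cultivated replicate 1, which held all 3 counts, it was at least 769 against a floor of 3 counts over the group.

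YSL15, which imports iron bound to mugineic acids, YSL2, which carries iron bound to nicotianamine, and NAAT1, an enzyme of mugineic acid synthesis, fell, with log2 fold changes of −7.34, −7.65 and −7.34 (edgeR adjusted p = 0.0307, 0.0319 and 0.0317). Co-cultivated replicate 1 kept 326 counts of NAAT1, against 16 and 34 in co-cultivated replicates 2 and 3 and at least 12290 in each control library. These 3 genes passed the threshold without co-cultivated replicate 1 but not without control replicate 1, control replicate 3 or co-cultivated replicate 2 (edgeR adjusted p up to 0.107 for YSL15, 0.110 for YSL2 and 0.110 for NAAT1), and YSL2 and NAAT1 also not without co-cultivated replicate 3. Over the fits without 1 library, the log2 fold changes ran from −9.69 to −6.79 for YSL15. They ran from −10.6 to −7.11 for YSL2 and from −9.78 to −6.81 for NAAT1. The nicotianamine synthase genes NAS1 and NAS2 had log2 fold changes of −8.06 ± 1.89 and −7.95 ± 1.68 and missed the threshold (edgeR adjusted p = 0.0740 and 0.0581). Their estimated counts were not whole, so reads of this pair may have been divided between them. NAS3 was at −0.67 ± 0.42 (edgeR adjusted p = 0.419). The remaining 5 called members are listed as IMA1 (Os01g0647200), DMAS1 (Os03g0237100), ENA1 (Os11g0151500), HRZ1 (Os01g0689451) and HRZ2 (Os05g0551000), with log2 fold changes of −9.52, −4.76, −5.14, −2.86 and −2.34. Their edgeR adjusted p were 0.000744, 0.00325, 0.00330, 0.00516 and 0.0427. The loci listed as DMAS1, ENA1, HRZ1 and HRZ2 were not among the named genes, so their calls were not followed with 1 library left out.

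Of the 4 members of the iron excess list, 3 were called higher, also adjusted over the list alone, and the list is too short for camera. VIT2 was higher in all 3 co-cultivated libraries, with 5396, 7744 and 6589 counts against 41 to 122 in the control libraries. The loci listed as the ferritins FER1 (Os11g0106700) and FER2 (Os12g0106000), which store iron, rose by log2 fold changes of 2.41 ± 0.24 and 2.44 ± 0.41 (edgeR adjusted p = 0.00516 and 0.0312). Their estimated counts were not whole, so the reads of these loci may have been shared, and the call of FER2 was lost without control replicate 1 or any 1 co-cultivated replicate (edgeR adjusted p up to 0.127). VIT1 was at −0.32 ± 0.60 (edgeR adjusted p = 0.802).

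**Figure D2:**
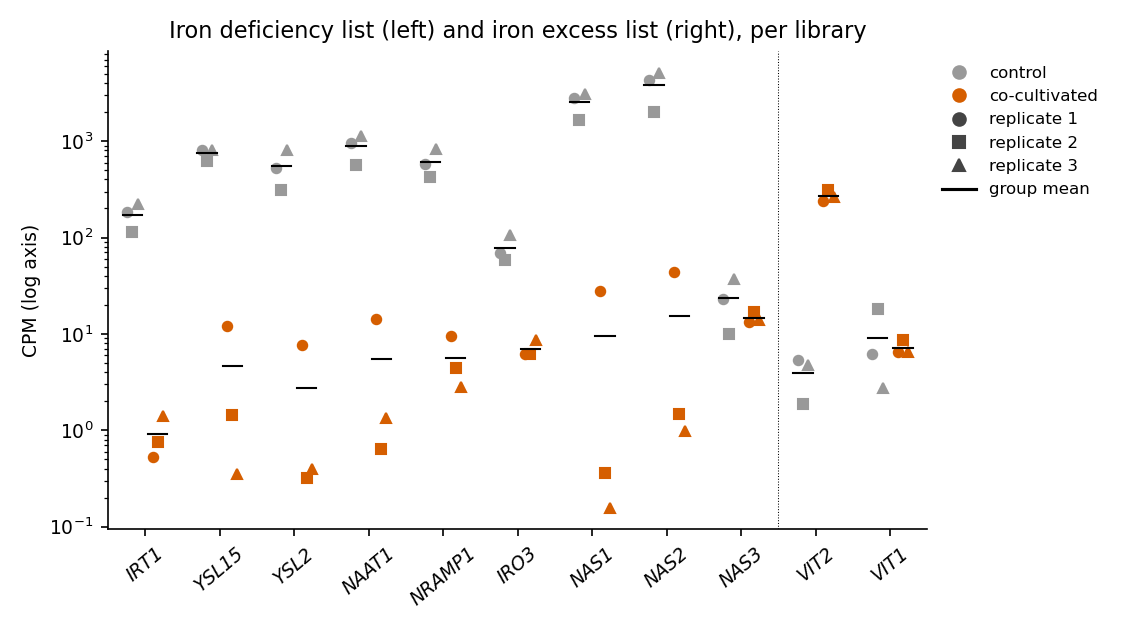
CPM on a log axis of 9 members of the iron deficiency list and of VIT2 and VIT1 of the iron excess list, for each of the 3 control (grey) and 3 co-cultivated (orange) libraries, with marker shape for the replicate and a black line for the group mean. IRT1 lies at 172 CPM in the control group and 0.906 CPM in the co-cultivated group, VIT2 at 3.98 and 270 CPM, and co-cultivated replicate 1 stays above the other co-cultivated libraries for YSL15, YSL2, NAAT1, NRAMP1, NAS1 and NAS2.

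The phosphate starvation list was higher by camera (adjusted p = 3.20e-05), but did not pass with an estimated correlation (adjusted p = 0.658). Of 15 tested members, 3 were called higher and 0 lower. Adjusted over the list alone, 10 were higher and 1 lower, and 14 of 15 had a positive fold change (median 1.26). SPX2, a gene of phosphate sensing, rose from 5.41 ± 1.27 to 22.5 ± 8.97 CPM (SD, n = 3), a log2 fold change of 2.05 ± 0.34, and PT6, a phosphate transporter gene, from 0.703 ± 0.509 to 11.0 ± 6.26 CPM, a log2 fold change of 3.95 ± 0.70 (edgeR adjusted p = 0.0301 and 0.0359). The locus listed as the non-coding RNA IPS1 (Os03g0146800) rose by 5.34 ± 0.49 (edgeR adjusted p = 0.00417). SPX3, SPX5 and PT2 stood at 2.74, 3.13 and 2.07 with edgeR adjusted p of 0.0573, 0.0576 and 0.0608. The member with a negative fold change, listed as PHO2 (Os05g0557700), stood at −1.11 (edgeR adjusted p = 0.0539). These counts take signs alone and not whether a member promotes or restrains the response. SPX2 and PT6 lost their calls without control replicate 1, co-cultivated replicate 1 or co-cultivated replicate 2, SPX2 also without control replicate 3 and PT6 without control replicate 2 (edgeR adjusted p up to 0.121 and 0.146). PT6 was not called by limma-voom. With a replicate block neither PT6 nor SPX2 was called (edgeR adjusted p = 0.0815 and 0.0656).

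Nitrogen and potassium genes gave fewer calls. In the nitrogen assimilation list, 1 of 12 tested members was called higher and 4 were higher adjusted over the list alone, with a camera adjusted p of 0.0144, and of 0.658 with an estimated correlation. The called member, listed as the nitrate reductase NIA2 (Os02g0770800), rose from 6.10 ± 2.25 to 248 ± 66.5 CPM (SD, n = 3), a log2 fold change of 5.34 ± 0.37 (edgeR adjusted p = 0.00149), and NIA1 was at 0.86 ± 0.27 (edgeR adjusted p = 0.144). With checked symbols alone, which keep 6 of the 12 members and leave out NIA2 and others together, the list's camera adjusted p was 0.527, and without control replicate 2 or co-cultivated replicate 2 it was 0.154 or 0.0561. In the nitrogen uptake list, 0 of 13 tested members were called by edgeR, 2 higher by DESeq2 and 0 by limma-voom. By edgeR, 4 had an unadjusted p under 0.05 and 2 were higher adjusted over the list alone. The camera adjusted p of this list was 0.393. The member with its smallest p, listed as the nitrate transporter NRT1.1B (Os10g0554200), was at 3.04 ± 0.62 (edgeR adjusted p = 0.0525). HAK1, a high-affinity potassium transporter gene, rose from 238 ± 94.6 to 760 ± 143 CPM, a log2 fold change of 1.68 ± 0.32 (edgeR adjusted p = 0.0465), the single call in the potassium and sulfate list of 6. Adjusted over that list alone, 3 members were higher and AKT1, a potassium channel gene, was lower; the list's camera adjusted p was 0.455. The HAK1 call was lost with upper-quartile scaling, with a replicate block and without control replicate 1 or any 1 co-cultivated replicate (edgeR adjusted p up to 0.171).

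The aquaporin and silicon list was higher by camera (adjusted p = 4.07e-05), but did not pass with an estimated correlation (adjusted p = 0.658). All 13 tested members had a positive fold change, from 0.03 to 1.22, with a median of 0.72. The silicon transporter genes LSI1 and LSI2 stood at 425 ± 145 against 896 ± 268 CPM and 615 ± 114 against 1218 ± 366 CPM (edgeR adjusted p = 0.147 and 0.123), and the water channel gene PIP2;2 at 547 ± 139 against 919 ± 207 CPM (edgeR adjusted p = 0.175). By edgeR, 0 members were called, over all loci or adjusted over the list alone, and 8 had an unadjusted p under 0.05; DESeq2 called 2 and limma-voom 0. The 3 root hair markers gave 0 calls by edgeR, 2 at an unadjusted p under 0.05, 2 calls by DESeq2, 0 by limma-voom and 2 higher adjusted over the list alone. CSLD1, a cellulose synthase-like gene of root hairs, was at 1.65 ± 0.41 and EXPA17, an expansin gene, at 2.63 ± 0.71 (edgeR adjusted p = 0.0847 and 0.103). EXPA17 held 111, 105 and 18 counts in co-cultivated replicates 1, 2 and 3, against 8 to 16 in the control libraries.

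Among hormone lists, the jasmonate, cytokinin and auxin lists were higher by camera (adjusted p = 4.07e-05, 0.00881 and 0.0411). None of these 3 passed with an estimated correlation (adjusted p = 0.658 for each). The jasmonate list had 13 positive fold changes of 13 tested (median 0.61). Its mean log2 CPM was 7.57 and 7.51 in co-cultivated replicates 1 and 3. In co-cultivated replicate 2 this mean was 6.77, against 6.44 to 6.77 in the control libraries. The jasmonate list had 0 calls by edgeR, with 8 members at an unadjusted p under 0.05, 4 calls by DESeq2 and 0 by limma-voom. Adjusted over the list alone, 4 were higher. Its members with the smallest p were AOC, an enzyme of jasmonate synthesis, at 0.61 ± 0.14, and the JAZ repressor genes JAZ11 and JAZ12 at 1.32 ± 0.34 and 1.14 ± 0.31 (edgeR adjusted p = 0.0730, 0.0927 and 0.103). In the cytokinin list, 7 of 7 were positive (median 0.85). RR1, a response regulator gene induced by cytokinin, was called higher at 2.03 ± 0.34 (edgeR adjusted p = 0.0312), and 3 members were higher adjusted over the list alone. In the auxin list, 9 of 14 were positive (median 0.33, or 0.19 without control replicate 3). GH3-2, which conjugates auxin to amino acids, was called higher at 1.79 ± 0.21 (edgeR adjusted p = 0.00945) and was 1 of 3 members higher adjusted over the list alone. GH3-2 was lost without control replicate 1 (edgeR adjusted p = 0.0663), and RR1 without control replicate 1, control replicate 3, co-cultivated replicate 1 or co-cultivated replicate 2 (edgeR adjusted p up to 0.137). The list calls were lost without co-cultivated replicate 2 for cytokinin and auxin (camera adjusted p = 0.0561 for both), and for auxin also without control replicate 3 or co-cultivated replicate 1 (0.130 and 0.0770) and with a filter of 1 CPM or none (0.105 and 0.0582).

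The other hormone lists did not pass camera. In the ethylene list, with a camera adjusted p of 0.439, 1 of 11 members was called. This was ERS2, an ethylene receptor gene, which rose from 25.0 ± 1.54 to 55.9 ± 9.85 CPM (SD, n = 3), a log2 fold change of 1.16 ± 0.17 (edgeR adjusted p = 0.0201). In the gibberellin list (camera adjusted p = 0.793), 1 of 7 was called. This locus is listed as GA20ox1 (Os03g0856700), an enzyme of gibberellin synthesis, and fell from 54.8 ± 14.8 to 9.96 ± 4.99 CPM (log2 fold change −2.46 ± 0.39, edgeR adjusted p = 0.0261). In the strigolactone and karrikin list (camera adjusted p = 0.439), 1 of 8 was called, listed as MAX1a (Os01g0700900), at 1.88 ± 0.37 (edgeR adjusted p = 0.0492). The abscisic acid and water deficit list of 9 had 0 calls by edgeR and limma-voom, 1 by DESeq2, 1 member at an unadjusted p under 0.05 and a camera adjusted p of 0.516. Adjusted over each list alone, 1 member passed in each of the ethylene, gibberellin and strigolactone lists and 0 in the abscisic acid list. All 3 calls were lost without control replicate 1 and without co-cultivated replicate 1 (edgeR adjusted p up to 0.103 for ERS2, 0.132 for GA20ox1 and 0.156 for MAX1a). ERS2 was also lost without co-cultivated replicate 2, GA20ox1 without co-cultivated replicate 3, and MAX1a without control replicate 3 or co-cultivated replicates 2 or 3, with the robust fit and under every other scaling tried. With a replicate block the MAX1a call was lost as well (edgeR adjusted p = 0.0553).

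Genes of microbial symbiosis were measured at 3 of 6 list members. CYCLOPS, which acts in the common symbiosis pathway, rose from 3.00 ± 0.614 to 7.96 ± 1.502 CPM (SD, n = 3), a log2 fold change of 1.41 ± 0.25 (edgeR adjusted p = 0.0369), and CCaMK, the calcium-dependent kinase of that pathway, was at 1.53 ± 0.33 (edgeR adjusted p = 0.0595). The other tested member, listed as NSP2 (Os03g0263300), was at 2.02 ± 0.76 with overlapping groups (edgeR adjusted p = 0.195). All 3 were higher adjusted over the list alone. The members not tested held few counts. The locus listed as AM1 (Os04g0134800) held 0 in all 6 libraries. PT11 held 2, 7 and 0 in the control and 0, 0 and 3 in the co-cultivated libraries. The locus listed as NSP1 (Os03g0408600) held 2, 0 and 3 against 16, 10 and 3. The CYCLOPS call was lost in every fit without 1 library except that without control replicate 2 (edgeR adjusted p up to 0.159). It was also lost with a replicate block (edgeR adjusted p = 0.0700). The phenylpropanoid and flavonoid list had 0 calls by edgeR, 5 at an unadjusted p under 0.05, 5 calls by DESeq2 and 0 by limma-voom. Adjusted over the list alone, 5 of 11 were higher. Its median was 0.35 and its camera adjusted p 0.0146 (0.833 with an estimated correlation). Without co-cultivated replicate 1 or 3 the camera adjusted p was 0.139 or 0.0722. The median was 0.74 without co-cultivated replicate 2 and 0.56 without control replicate 1. The list's mean log2 CPM was 8.38 and 8.27 in co-cultivated replicates 1 and 3. In co-cultivated replicate 2 this mean was 7.43, below the control libraries (7.46 to 7.63). The diterpenoid phytoalexin list of 9 and the pathogenesis and immunity list of 6 had 0 calls by edgeR, over all loci or adjusted over the list alone, with 4 and 0 members at an unadjusted p under 0.05. DESeq2 called 3 and 0 of them, limma-voom 0 in each, and the camera adjusted p were 0.146 and 0.891. The mean log2 CPM of the former lay below all 3 control libraries in co-cultivated replicate 2.

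**Figure D3:**
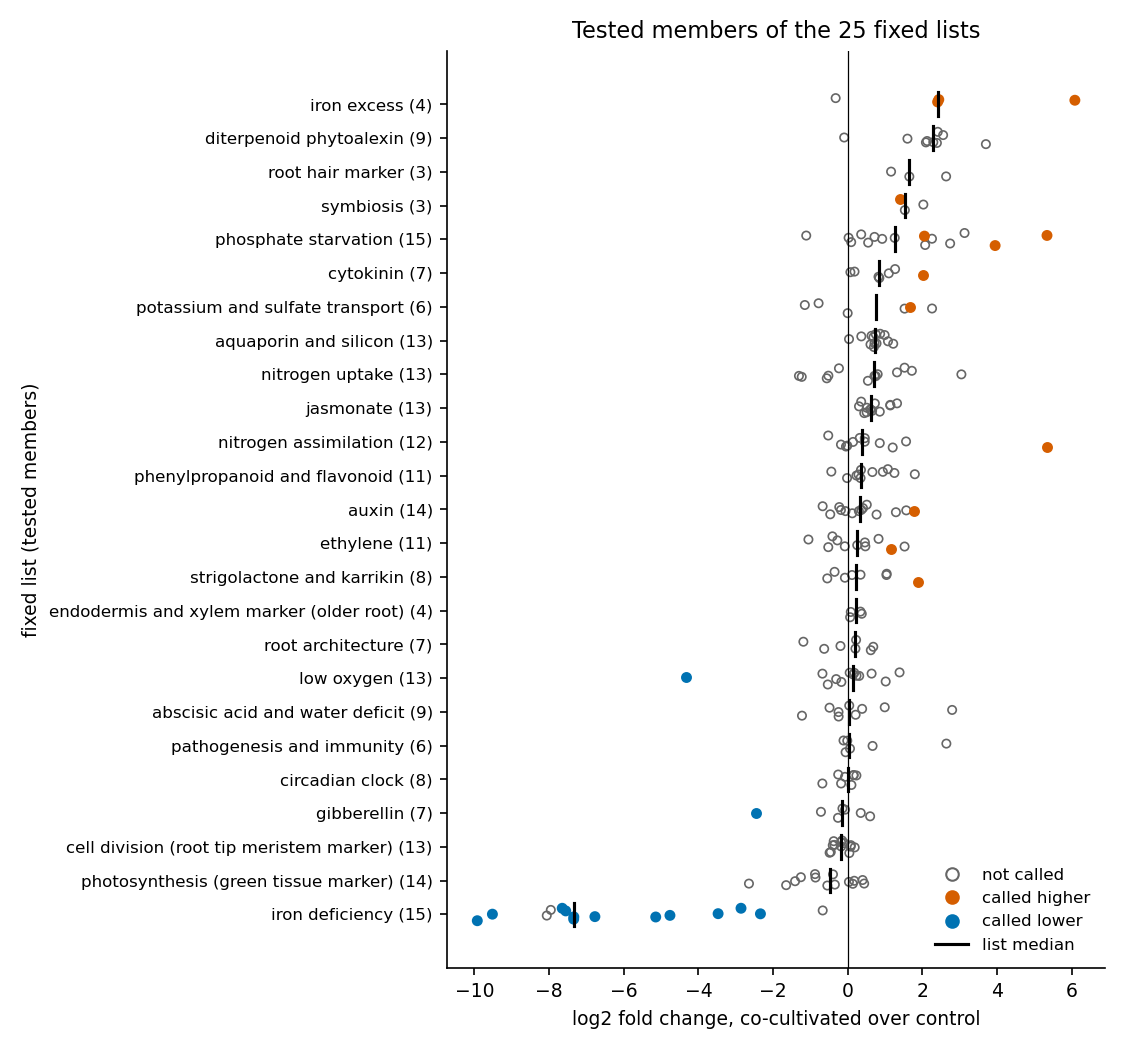
Log2 fold change (co-cultivated over control) of every tested member of the 25 fixed lists, with the number tested in brackets, filled points for called members (orange higher, blue lower), open points for the rest and a black bar at the list median. The iron deficiency list has a median of −7.34 and the aquaporin and silicon list one of 0.72.

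HB2 was the single call among 13 low oxygen genes, also adjusted over the list alone. It fell from 499 ± 298 to 24.6 ± 5.40 CPM (SD, n = 3), a log2 fold change of −4.34 ± 0.46 (edgeR adjusted p = 0.00652), and stayed called in each fit without 1 library. The fermentation genes ADH1 and ADH2 stood at −0.17 ± 0.39 and 0.64 ± 0.39 (edgeR adjusted p = 0.841 and 0.399), and the list had a median of 0.14 (0.03 to 0.21 without 1 library), a mean of −0.16 and a camera adjusted p of 0.891 in the direction of lower. Cell division genes, markers of the root tip meristem, had 0 calls in 13 by each of edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.815). Their mean log2 CPM was 5.04 ± 0.654 in the control and 4.96 ± 0.158 in the co-cultivated group (SD, n = 3). Control replicate 2 was highest of all libraries in this measure, at 5.73, and control replicate 3 lowest, at 4.44. The endodermis and xylem markers of older root tissue had 0 calls by edgeR in 4 (median 0.21, from 0.05 without control replicate 2 to 0.65 without control replicate 3), the root architecture list 0 in 7 (camera adjusted p = 0.936) and the circadian clock list 0 in 8 (camera adjusted p = 0.793). In these lists 0, 1 and 1 had an unadjusted p under 0.05, DESeq2 called 0, 1 and 0, and limma-voom 0 in each. Adjusted over the list alone, edgeR called 0 members of these 3 lists, of the cell division list and of the photosynthesis list. The photosynthesis list, a marker of green tissue, had 0 calls in 14 by edgeR, DESeq2 and limma-voom, and 2 at an unadjusted p under 0.05. Its median was −0.47 and its camera adjusted p 0.0411 in the direction of lower, or 0.878 with an estimated correlation. The call was lost in 9 of the 16 other settings. The median turned to 0.14 with a filter of 1 CPM and to 0.02 without control replicate 3, and stood at −0.84 without control replicate 2 and at −0.04, −0.02 and −2.19 without co-cultivated replicates 1, 2 and 3; it was −1.19 with limma-voom. Co-cultivated replicate 3 differed from the other co-cultivated libraries: GLK1, a transcription factor gene of chloroplast development, held 3, 8 and 103 counts in the co-cultivated libraries and 14, 28 and 53 in the control libraries.

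The loci at the extremes of the table have no name here. Os12g0236200 and Os12g0236225, neighbours on chromosome 12, held 666 and 709 counts over the control libraries and 0 over the co-cultivated ones, at least 236-fold and 251-fold lower against a floor of 3 counts over the group. With 1 library left out these bounds ran from 147 to 296 and from 164 to 289, the lowest for Os12g0236200 without control replicate 3, which held 396 of its counts. The estimated counts of Os12g0236225 were not whole. Os10g0444600 held 0 counts in the control group and 509 in the co-cultivated group, at least 159-fold higher. The 3 co-cultivated libraries held 303, 165 and 41 of these, and the bound was 93.6 without replicate 1 and up to 225 without replicate 3 of that group. Os06g0325200 held 2 and 285, a ratio of 134 with a 95% counting interval of 36.7 to 1111.3, and of 83.5 to 190 with 1 library left out. The edgeR adjusted p were 0.0191 for Os12g0236200, 0.00406 for Os12g0236225, 0.0453 for Os10g0444600 and 0.0277 for Os06g0325200. Whether these calls hold with 1 library left out was not tested.

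The libraries separated by group on the first principal component of log2 CPM, with 48.1% of the variance. The next component, with 24.3%, set control replicate 2 apart from control replicate 3. Control replicates 1, 2 and 3 lay at 10.9, −77.6 and 62.5 on it. The co-cultivated libraries lay in the same order, at 11.5, −24.2 and 16.9. Spearman correlations over loci ran from 0.947 to 0.984 within groups and from 0.927 to 0.955 between them.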

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

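Settings were run on 80 named genes, 21 lists and the counts of calls, as fixed for each: lists were not tested with DESeq2, limma-voom or the robust fit, the 2 thresholds were applied to the counts of loci alone, and estimated correlation and fry to lists alone. A cell-division covariate, lists of checked symbols alone and low-count ratios without 1 library were added after seeing the data. The counts of 360 higher and 288 lower became 1486 and 938 with DESeq2, which called all 648 loci among them, 1431 and 956 with the cell-division covariate, which did the same, and 54 and 83 at an adjusted p under 0.01. Leaving out 1 library gave 56 to 361 higher, 83 to 493 lower and 6 to 10 lists in place of 9. Every other scaling, filter or fit kept both counts within 1.5 times. Lists called were 0 with an estimated correlation and 1 with fry. The replicate numbers were not taken to pair the libraries, since the labels do not tie same-numbered libraries to each other. Deviations of same-numbered libraries correlated at 0.0571, 0.146 and 0.174. These values are low but all positive, and the second principal component ordered both groups alike by replicate number. A pairing is therefore not excluded. Control replicates 2 and 3 were closest to the co-cultivated library of their own number, control replicate 1 to co-cultivated replicate 2. A replicate block gave 403 higher and 296 lower, of which 250 and 219 were among the main calls, and 9 lists. With it PT6, SPX2, HAK1, CYCLOPS and the locus listed as MAX1a had edgeR adjusted p of 0.0815, 0.0656, 0.0701, 0.0700 and 0.0553. The diterpenoid list was called (camera adjusted p = 0.0104) and the photosynthesis list was not (0.186). LSI1, GH3-8, RR6 and the locus listed as NCED4 (Os07g0154100) gained a call, and no other call of a named gene or list changed.

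Of 23 called named genes, 10 were called in each of the 6 fits without 1 library: IRT1, IRT2, NRAMP1, IRO3, HB2, VIT2 and the loci listed as IMA1, FER1, NIA2 and IPS1. Of 480 gene values without 1 library, 48 lost their call, 9 gained one and 5 changed sign; of 872 in the other settings 11 lost it, 56 gained one and 0 changed sign. The sign changes fell on uncalled genes, whose log2 fold changes without 1 library ran from −0.74 to 0.086 for MCM5, from −0.19 to 0.53 for CESA4 and from −0.58 to 3.21 for PBZ1; the cause was not tested.

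List directions turned for 8 lists that were not called. Without 1 library their camera adjusted p ran from 0.0152 to 0.944 (abscisic acid), 0.0188 to 0.970 (cell division, higher at 0.0437 without control replicate 2), 0.293 to 0.982 (circadian clock), 0.123 to 0.855 (ethylene), 0.154 to 0.944 (gibberellin), 0.688 to 0.992 (low oxygen), 0.196 to 0.992 (pathogenesis) and 0.783 to 0.970 (root architecture). Low oxygen also turned with the replicate block (0.756) and checked symbols alone (0.899), and root architecture with fry (0.912), no filter (0.814), a filter of 1 CPM (0.867), the block (0.766) and the covariate (0.950). The causes were not tested. Depth limits the low loci: 3 counts or fewer in a group leave a ratio with a wide interval.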

Other observations

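The test of iron storage genes, the cell-division covariate, the marker lists set beside it and the checked-symbol lists were chosen after the results they bear on were seen; the other tests were fixed before theirs.

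Diterpenoid phytoalexin genes, which make momilactones and related defence compounds, differed widely between the co-cultivated libraries. Of 9 tested members, 8 had a positive fold change (median 2.29, from 1.42 to 2.86 without 1 library), with 0 called by edgeR, over all loci or adjusted over the list alone, 4 at an unadjusted p under 0.05, 3 called by DESeq2, 0 by limma-voom and a camera adjusted p of 0.146. The mean log2 CPM of the list was 3.88 and 4.36 in co-cultivated replicates 1 and 3 but 0.53 in co-cultivated replicate 2, below the control libraries (0.85 to 2.19). CPS4, a diterpene cyclase gene of the momilactone cluster, held 1448, 62 and 3028 counts in the 3 co-cultivated libraries and 170 to 412 in the control libraries. Without co-cultivated replicate 2 the list's camera adjusted p was 8.63e-09, the lowest over all settings. The highest, 0.878, was that of all 6 libraries with the estimated correlation, which was 0.691. The pathogenesis-related gene PBZ1 held 561, 74 and 9053 counts in the same 3 libraries.

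The fall of the iron deficiency list came with a rise of 3 of the 4 iron excess members. A cell-division score stood at 5.04 ± 0.654 in the control and 4.96 ± 0.158 in the co-cultivated group (SD, n = 3). Adding it to the fit left the list's median log2 fold change at −7.47, against −7.34 without it. Since the score's means were close, it could move the group difference little, and this fit alone does not decide the question. The cell division list would have to fall as far if these genes were lost with dividing cells. Its median was −0.18 (−0.45 to 0.30 without 1 library), which argues against such a loss as the cause. The endodermis and xylem markers of older tissue had a median of 0.21 (0.05 to 0.65), far smaller in size than the fall of the iron list. Whether the share of older tissue differed is not settled by these markers. The 3 calls in the iron excess list are in line with the hypothesis that the co-cultivated roots held more iron than the control roots, which these data do not measure. The design leaves open whether the fern, the cover on the control boxes, or a difference in the solution that follows from either is responsible.

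The aquaporin and silicon list and the phosphate starvation list were higher by camera, but not with an estimated correlation or by fry (adjusted p = 0.658 and 0.151 for both). Root tips cut with less meristem in the co-cultivated group could give this. With the cell-division score in the fit the list medians were 1.02 and 0.997 times their values without it. The score's means were close in both groups, so this fit could change the medians little and does not decide the question. Without control replicate 2 the cell division list had a median of 0.30 (camera adjusted p = 0.0437), and the aquaporin and phosphate medians were 0.59 and 1.11. Without control replicate 3 it had one of −0.45 (0.0188), and they were 0.70 and 1.17. Both lists kept positive medians whichever way the cell division list leaned. Both fits share the same co-cultivated libraries and each drops 1 control library, so they do not decide on a different share of dividing tissue. These camera p rest on the preset correlation of 0.01. Over all 6 libraries the cell division list's estimated correlation was 0.952 (camera adjusted p = 0.943). The root hair markers had 3 of 3 positive fold changes (median 1.65). The endodermis and xylem markers had 4 of 4 (median 0.21), with edgeR adjusted p from 0.611 to 0.963, and CESA4 changed sign in 3 fits without 1 library. A larger share of older tissue, which the cell-division score does not measure, stays open.

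Called loci lay next to each other more often than chance placement gives. There were 50 pairs of consecutive loci called in the same direction, 24 higher and 26 lower, over 90 loci, against a median of 9 and a highest value of 22 in 10000 random placements. In 8 of the 50 pairs (16%) both loci held estimated counts that were not whole, against 2.48% of all consecutive tested pairs. Most of these 8 pairs lay in a single run of consecutive loci, from Os07g0429700 to Os07g0432800, so they are not separate cases. Reads divided between similar neighbours could account for those 8. The other 42 lacked this sign in at least 1 locus, which does not exclude divided reads, as the counting tool is not known here. What places the other 42 side by side was not tested. Overlapping gene models that count the same transcript stay open, as no coordinates of this build were used here.

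There are 10 ways to split the 6 libraries 3 against 3, too few for a share under 0.05. The real split, the 1 with as many calls, gave 648 called loci, and the highest of the others gave 0.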
